A study of Mus musculus with 16 samples.

How the data were processed

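Bulk RNA sequencing of whole ovary and whole kidney was analysed, with 4 libraries in each of 4 groups (2 organs, each with PT-2385 or vehicle). Per the labels' protocols, mice received PMSG and hCG during the treatment. Ovary RNA was isolated with a column kit and kidney RNA with Trizol, and between 1.8 and 5 µg of RNA per sample entered a stranded polyA library preparation. Because the RNA isolation differed between organs, no test compared levels between organs, only responses; levels of tissue markers in both organs are given as a check of identity.

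The values are read pair counts per gene, made before they were deposited by featureCounts 2.0.6 on paired reads over exons grouped by gene, with the GENCODE vM27 basic annotation, per the file headers. Per the submitters' processing notes, reads were checked with FastQC and aligned with STAR to GRCm39; their versions were not given in the sources used here. No strand option stands in the recorded command, so reads of genes that overlap on opposite strands could not be separated. Of 120 named genes checked, 32 shared any exon bases with another gene model and 8 shared 20% or more. All 16 columns were used and none belonged to another sample.

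Gene symbols and biotypes came from GENCODE M21 by gene identifier, which covered 52083 of 55359 identifiers (94.1%). Coordinates came from the count files (GRCm39). Counts without a symbol made up between 0.681% and 3.14% of a library. Assigned read pairs ran from 12.7 to 43.3 M (1 M is 1e6) per library, the lowest in kidney PT-2385 replicate 2 and the highest in kidney PT-2385 replicate 3. The file name of the latter holds another flow-cell code than the rest. The file of ovary vehicle replicate 3 carries the number 5. Both libraries were kept in the groups the labels give.

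Each organ was tested alone with the quasi-likelihood test of edgeR 4.0.16 (robust, R 4.3.3, limma 3.58.1) after TMM scaling. Genes passed filterByExpr at its defaults (count 10, total 15), which left 18125 genes in ovary, 17763 in kidney and 19977 for the interaction. The interaction, the response in ovary minus that in kidney, was tested over all 16 libraries. P-values were adjusted by Benjamini-Hochberg within each comparison and called under 0.05. Each organ had 6 residual degrees of freedom. CPM are given after TMM scaling within the organ for tested genes, and over all 16 libraries for single tissue markers. They are given without TMM scaling for Epo and for summed proximal tubule markers in ovary. Where a spread is given it is mean ± SD of 4 libraries.

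The 34 gene lists, of 14 to 33 members, were fixed before the data were examined, and 1 member had no match. Some genes stand in more than 1 list. They were tested with camera at a preset correlation between genes of 0.01 where at least 5 members were tested, and again with an estimated correlation and with fry. Members were also adjusted over the list alone. List scores per library were medians over members of log2 CPM (prior count 2) minus the vehicle mean of each member, and were compared by exact two-sided permutation over 70 groupings.

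Genes were named by a fixed rule: (a) Epas1, Hif1a, Arnt, Pgr, Vegfa and Epo always; (b) the 10 called genes with the largest rise and the 10 with the largest fall among those with a proper symbol, at least 2 CPM in the higher group and no overlap between groups; (c) up to 4 members with the smallest p from each list that was called or had a called member, and at most 2, as values only, from other lists; (d) where fewer than 10 genes were called, the 10 with the smallest p; (e) for the interaction the 8 with the smallest p. Markers of other tissues came from the fixed lists. Some genes that the rule selects are not reported here.

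Alternatives were median-ratio and upper-quartile scaling, DESeq2 1.42.0, limma-voom, the legacy quasi-likelihood test, no filter, a filter of 1 CPM in 4 libraries, a fit without mitochondrial and haemoglobin genes, 1 surrogate variable (sva 3.50.0), a block on replicate number, a fit of all 16 libraries and each library left out. The fit without both libraries with deviating file names was added after the data had been seen. Figures used Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9, and random steps used seed 1.

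The tests were tested on simulated data with the libraries' own spread. In ovary (17870 genes), 52.2%, 70.1% and 93.9% of 67, 67 and 66 genes changed 1.5-, 2- and 4-fold were recovered, and 4.8% of calls were false. In kidney (17521 genes) these were 64.2%, 91.0% and 92.4%, with 10% of calls false. For the interaction (19709 genes) they were 38.8%, 65.7% and 78.8%, with 5.8% false. A list of 20 members changed 1.5-fold had camera adjusted p of 3.76e-30, 4.11e-35 and 3.72e-32, and of the unchanged lists 1 of 34, 0 of 32 and 0 of 34 were called. Genes were drawn independently, so these lists lacked the correlation between members of the real ones. The simulation therefore does not show how often camera calls unchanged lists in the real data. Splits of the real libraries called a median of 13 lists in ovary, 7 in kidney and 10 for the interaction.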

Results

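RNA was measured in whole ovary and whole kidney from 21-day-old female CBAF1 mice of wild-type genotype. PT-2385 is a small molecule that binds HIF-2α, the hypoxia-inducible transcription factor encoded by Epas1, and keeps it from pairing with its partner ARNT. Mice received 7.5 mg/kg PT-2385, or its vehicle of 5% DMSO in saline, by intraperitoneal injection every 12 h over 4 days. Within those days PMSG (5 IU), a gonadotrophin that drives follicles to grow, was followed after 48 h by hCG (5 IU), which stands in for the LH surge and triggers ovulation. Both organs were taken 13 h after hCG. There were 4 libraries in each of the 4 groups, 16 in total, and nothing in the labels says that the libraries of a group came from separate animals, so the p-values below measure the spread between these samples.

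Assigned read pairs per library came to 29.7, 29.8, 33.6 and 29.5 M (1 M is 1e6) in ovary with vehicle (replicates 1 to 4) and to 17.2, 26.1, 25.7 and 32.0 M in ovary with PT-2385. In kidney they came to 26.3, 27.0, 23.3 and 26.8 M with vehicle and to 23.0, 12.7, 43.3 and 26.6 M with PT-2385. Tissue identity was clear in the counts. Foxl2, the granulosa cell transcription factor, and Zp3, a zona pellucida protein of the oocyte, had 0 counts in each of the kidney libraries and reached 103 and 80.2 CPM (counts per 1e6 counts) in ovary. Kap, an androgen-regulated proximal tubule protein, lay between 12000 and 15100 CPM in kidney and at 0.728 CPM or less in ovary, except for 30.6 CPM in ovary vehicle replicate 1.

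The transcripts of the drug's target and its partners came first, as a check of the system. In ovary, Epas1 (chromosome 17, 87061128 to 87140838, GRCm39) stood at 171 ± 15.8 CPM with vehicle and 165 ± 1.32 CPM with PT-2385 (mean ± SD, n = 4), a log2 fold change of −0.05 (SE 0.0718, adjusted p = 0.818, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). In kidney it stood at 195 ± 9.05 and 197 ± 8.14 CPM (log2 fold change 0.01, adjusted p = 0.890, edgeR). Hif1a, which encodes the related HIF-1α, and Arnt, the shared partner, passed the test in neither organ, with log2 fold changes of 0.17 and 0.02 in ovary and of 0.03 for each in kidney. Vegfa, the angiogenic growth factor induced by hypoxia, had log2 fold changes of 0.04 in ovary and 0.10 in kidney, also short of the threshold. Pgr, the progesterone receptor gene that LH induces in granulosa cells, measured 2.14 ± 0.589 CPM with vehicle and 4.15 ± 1.63 CPM with PT-2385 in ovary (log2 fold change 0.93, SE 0.279, adjusted p = 0.215, edgeR). The compound acts on the protein, so these transcript levels do not measure how far HIF-2α was blocked.

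Epo, which encodes erythropoietin and is driven by HIF-2α in kidney interstitial cells, had too few counts to enter the test. All 4 vehicle kidneys together held 7 counts and the 4 PT-2385 kidneys 45, or 0.0657 ± 0.0476 against 0.376 ± 0.233 CPM (two-sided exact permutation p = 0.0571, where the smallest p of this design is 0.0286). In ovary the totals were 1 and 2 counts.

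The first comparison asked what PT-2385 did to the ovary at ovulation. Of 18125 genes tested, 9 passed an adjusted p of 0.05, 1 higher and 8 lower with PT-2385. Eif2ak2, the kinase PKR that senses double-stranded RNA (chromosome 17, 79159993 to 79190002), fell from 51.4 ± 5.18 to 29.5 ± 3.37 CPM (n = 4), to 0.575 of its vehicle level (log2 fold change −0.80, SE 0.0943, adjusted p = 0.0186, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Ddx60, an antiviral RNA helicase (chromosome 8, 62381123 to 62491278), fell to 0.423 of its vehicle level, from 8.64 ± 1.67 to 3.62 ± 0.702 CPM (adjusted p = 0.0304, edgeR). Slc11a1, the divalent metal transporter of macrophage phagosomes (chromosome 1, 74414354 to 74425221), was the gene that rose, from 26.5 ± 3.18 to 41.6 ± 4.28 CPM (fold 1.57, log2 fold change 0.65, SE 0.0971, adjusted p = 0.0396, edgeR).

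Also lower in ovary were Trim34a, a tripartite motif protein, to 0.429 of vehicle, Cmpk2, a mitochondrial nucleotide kinase, to 0.484, Parp14, an ADP-ribosyltransferase, to 0.555, and Ifi204, a DNA sensor, to 0.614, with adjusted p between 0.0186 and 0.0461 (edgeR quasi-likelihood test, Benjamini-Hochberg). Gm6548, a processed pseudogene that ends next to Eif2ak2 on the same strand (chromosome 17, 79158221 to 79159385), fell by 0.79 on the log2 scale. It lay outside the rule for named genes and was chosen after its values were seen. The fixed list of interferon response genes moved with them. All 27 measured members had lower values with PT-2385, with a median log2 fold change of −0.90. Of these, 1 fell when adjusted over all genes and 22 fell when adjusted over the list alone. The list was called by camera (adjusted p = 3.73e-41), and its adjusted p = 0.302 with an estimated correlation between members. Ifit3 and Ifit3b, near-identical antiviral genes whose reads cannot be fully told apart, had log2 fold changes of −1.64 and −2.04, and Rsad2, the antiviral enzyme viperin, −1.50. These missed the threshold over all genes (adjusted p = 0.0565, 0.0605 and 0.0583, edgeR). Per library, the list score, the median over members of log2 CPM minus the vehicle mean of each member, was 0.134, −0.422, 0.0624 and 0.23 with vehicle and −0.866, −1.11, −1.21 and −0.441 with PT-2385 (two-sided exact permutation p = 0.0286, 0.352 after adjustment over all lists).

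**Figure D1:**
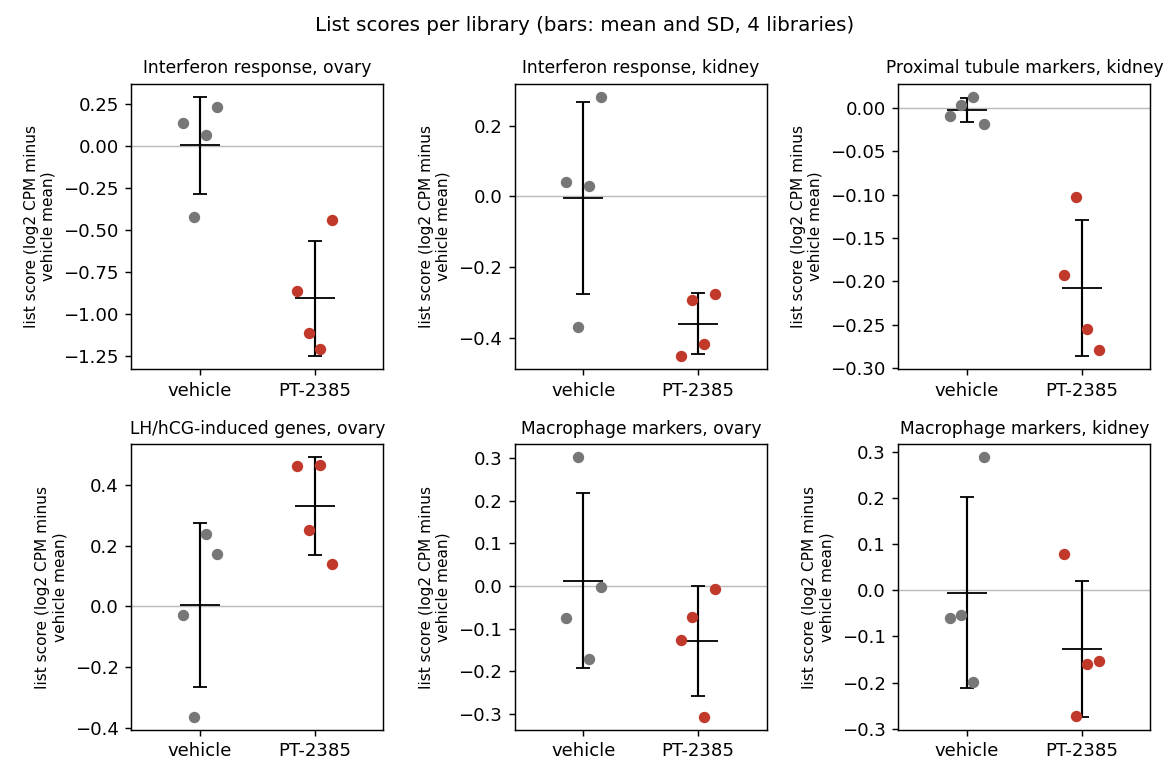
List scores, the median over members of log2 CPM relative to the vehicle mean of each member, for 6 pairs of list and organ; points are libraries, bars the mean and SD of 4. The ovary interferon scores lie between −0.422 and 0.23 with vehicle and between −1.21 and −0.441 with PT-2385, and the kidney proximal tubule scores of both groups do not overlap.

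These ovary calls depended on single libraries and on the test. The calls named here were all lost without vehicle replicate 1 (0 genes called), vehicle replicate 4 (0), PT-2385 replicate 1 (1), PT-2385 replicate 2 (0) or PT-2385 replicate 3 (0). All were kept without vehicle replicate 2 (58 called), vehicle replicate 3 (1060 called, 582 higher and 478 lower) or PT-2385 replicate 4 (56). With limma-voom, which kept 3 calls, Slc11a1 (adjusted p = 0.0662), Ddx60 (0.0649), Parp14 (0.0649), Cmpk2 (0.0672) and Ifi204 (0.0672) lost theirs. With the stricter filter, which kept 5, Slc11a1, Cmpk2 and Ifi204 did (adjusted p = 0.0508 each, edgeR). The log2 fold changes themselves moved little: Eif2ak2 lay between −0.88 and −0.74 and Ddx60 between −1.40 and −1.11 over all settings tried. At an unadjusted p of 0.05, 2375 genes passed, against 906 for a uniform p. However, 3 other splits of the same 8 libraries gave more (3257, 3378 and 3872), each with vehicle replicate 3 among 3 PT-2385 libraries. In 1260 genes (6.95%) the libraries of both groups did not overlap, against 2.86% by chance. Ovary vehicle replicate 3 stood apart in its nuclear noncoding RNAs, with Malat1, Neat1, Xist and Kcnq1ot1 at −1.27, −1.49, −1.16 and −1.42 log2 units from the mean of the other vehicle ovaries. Trim34a shares 23.5% of its exon bases with overlapping gene models, and counting was not stated to use strand, so reads of its partner cannot be separated.

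Genes of the ovulatory programme lay higher with PT-2385 as lists, although no member passed the test over all genes. These lists share members, such as Areg, which is in each of them, so they are not independent results. The list of genes induced by LH or hCG had a median log2 fold change of 0.28, with 27 of 32 members positive and 6 that rose when adjusted over the list alone (camera adjusted p = 1.5e-09; adjusted p = 0.615 with an estimated correlation). Its leading members were Adamts4, a protease that cleaves versican in the expanding follicle (115 ± 19.7 to 180 ± 30.2 CPM, n = 4), Btc, the EGF-like growth factor betacellulin, and Ptx3, a matrix protein of the cumulus. Their log2 fold changes were 0.65, 0.61 and 0.67 (adjusted p = 0.116, 0.213 and 0.214, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The cumulus expansion list had a median of 0.38, with 14 of 16 members positive and, adjusted over the list alone, 9 that rose and 1 that fell (camera adjusted p = 1.2e-07; adjusted p = 0.494 with an estimated correlation). Areg, the EGF-like factor amphiregulin that relays the LH signal to the cumulus, measured 3.27 ± 0.798 and 6.15 ± 2.19 CPM (log2 fold change 0.87). The list of progesterone receptor dependent granulosa genes had a median of 0.26 and 21 of 22 members positive, with 0 changed over all genes or adjusted over the list alone (camera adjusted p = 1.5e-05; adjusted p = 0.659 with an estimated correlation). Rgcc, a cell cycle regulator, and Prkg2, a cGMP-dependent kinase, had log2 fold changes of 0.39 and 0.57. Without vehicle replicate 2 the medians fell to 0.17 for the LH or hCG list and 0.11 for the progesterone receptor list, and without PT-2385 replicate 1 the latter fell to 0.17. The list scores of the vehicle libraries spread widely, and for the LH or hCG list both groups overlapped (two-sided exact permutation p = 0.114, 0.352 after adjustment over all lists).

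In ovary the lists of HIF-1 targets, HIF pathway components and unfolded protein stress genes were called on the higher side. That of targets preferred by HIF-2α was not called. The list of HIF-1 and glycolysis targets had a median log2 fold change of 0.19 with 30 of 33 members positive (camera adjusted p = 2.68e-10; adjusted p = 0.615 with an estimated correlation), and 0 members changed over all genes or adjusted over the list alone. Its leading members were Pfkfb3, which makes the main activator of glycolysis (101 ± 11.7 to 126 ± 8.16 CPM, n = 4), Slc2a1, the glucose transporter GLUT1, and Slc16a3, the lactate exporter MCT4. Their log2 fold changes were 0.32, 0.46 and 0.49 (adjusted p = 0.184, 0.215 and 0.238, edgeR quasi-likelihood test, Benjamini-Hochberg). The unfolded protein and amino acid stress list had a median of 0.17, with 23 of 26 members positive and 5 that rose adjusted over the list alone (camera adjusted p = 7.26e-08; adjusted p = 0.494 with an estimated correlation). Herpud1, which serves degradation at the endoplasmic reticulum, and Dnajb9, a chaperone of that compartment, led it with log2 fold changes of 0.54 and 0.37. The list of HIF pathway components had a median of 0.063 with 11 of 14 members positive (camera adjusted p = 0.049, and adjusted p = 0.708 with an estimated correlation). Among its members were Egln3, the prolyl hydroxylase PHD3 (log2 fold change 0.41), and Pgr (0.93). Pgr is also in the list of LH or hCG induced genes, so this call rests in part on an ovulatory gene. The call of HIF pathway components in ovary was lost without vehicle replicate 1 (camera adjusted p = 0.102), vehicle replicate 2 (0.35), PT-2385 replicate 2 (0.0917) or PT-2385 replicate 3 (0.109), and with the stricter filter (0.0779). Without vehicle replicate 2 the medians fell to 0.12 for HIF-1 and glycolysis targets, 0.10 for the unfolded protein list and 0.0021 for HIF pathway components. The last was 0.11 without vehicle replicate 3 and 0.036 without PT-2385 replicate 3. The list of targets preferred by HIF-2α was not called in ovary: its median was −0.0035, its mean 0.034, and camera placed it on the higher side (camera adjusted p = 0.64). Its members went both ways, with Adm, the vasodilator adrenomedullin, at a log2 fold change of −0.63 (36.2 ± 7.95 and 23.3 ± 1.81 CPM, adjusted p = 0.116, edgeR) and Egln3 at 0.41.

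Further ovary lists were called. Extracellular matrix and protease genes had a median log2 fold change of 0.17 with 25 of 31 positive (camera adjusted p = 7.26e-05; adjusted p = 0.659 with an estimated correlation). Mmp11, stromelysin-3, went the other way at −0.37. Cell cycle genes, among them Ccnb1, cyclin B1 (0.21), and Ube2c, a ubiquitin-conjugating enzyme of mitosis (0.30), had a median of 0.12 with 26 of 30 positive (0.00011, and adjusted p = 0.708 with an estimated correlation). Ube2c shares 22.8% of its exon bases with Tnnc2 on the opposite strand, so its reads may include those of that gene. Endothelial markers had a median of −0.12 with 7 of 28 positive (0.00298; adjusted p = 0.708 with an estimated correlation), including Flt4, the receptor VEGFR3 (−0.33), and Tek, the angiopoietin receptor (−0.47). The list named for kidney injury had a median of 0.14 with 15 of 21 positive (0.00436; adjusted p = 0.615 with an estimated correlation). It was led by Spp1, the secreted protein osteopontin (1536 ± 464 and 2600 ± 386 CPM, log2 fold change 0.76), and Serpina3n, an acute phase protease inhibitor (0.40). PPAR and fatty acid targets had a median of −0.12 with 4 of 21 positive (0.00436; adjusted p = 0.659 with an estimated correlation), led by Ehhadh, a peroxisomal β-oxidation enzyme (−0.63), and Cd36, a fatty acid carrier (−0.39). Immediate early and handling stress genes, called immediate early genes here, had a median of 0.17 with 19 of 27 positive (0.0131; adjusted p = 0.708 with an estimated correlation), although Dusp1, a phosphatase of MAP kinases, was at −0.52 and Hsph1, a heat shock protein, at 0.53. Macrophage and monocyte markers had a median of −0.15 with 3 of 18 positive (0.049; adjusted p = 0.708 with an estimated correlation), among them Cx3cr1, the fractalkine receptor (−0.51). Without vehicle replicate 2 the adjusted p was 0.238 for the cell cycle list, 0.132 for endothelial markers, 0.327 for immediate early genes and 0.388 for macrophage markers. The medians of these 4 lists were then 0.0505, −0.0526, 0.032 and −0.0736, and those of matrix genes, injury markers and PPAR targets 0.0997, 0.049 and −0.043. Without vehicle replicate 3 medians were 0.20 for the cell cycle, −0.19 for endothelial markers, 0.23 for injury markers and −0.075 for PPAR targets. Without PT-2385 replicate 3 they were −0.071 for PPAR targets and −0.082 for macrophage markers. Immediate early genes also lost their call without PT-2385 replicate 1 (0.149, median 0.106) or PT-2385 replicate 3 (0.169), and macrophage markers without vehicle replicate 4 (0.0571) or PT-2385 replicate 3 (0.251), with the stricter filter (0.0644) and with a block on replicate number (0.0506).

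The remaining ovary lists were not called, with camera adjusted p between 0.178 and 0.979. Among the cell types of the organ, median log2 fold changes were 0.058 for granulosa cell markers (camera, which weighs the test statistics, placed these lower), 0.040 for theca cell markers, 0.012 for oocyte markers and −0.0040 for steroidogenesis genes, where camera pointed higher. Hsd3b1, the enzyme that makes progesterone from pregnenolone, measured 3536 ± 1214 and 2273 ± 241 CPM (log2 fold change −0.64, adjusted p = 0.239, edgeR). Medians were 0.35 for neutrophil, −0.15 for lymphocyte, −0.11 for erythroid, −0.14 for adipocyte, 0.064 for fibroblast, −0.060 for pericyte and 0.039 for ovarian surface and oviduct markers, the last with a mean of −0.11. Medians were −0.0060 for xenobiotic metabolism, −0.044 for iron handling, −0.015 for cholesterol synthesis (camera pointed higher) and 0.028 for the circadian clock, where Arntl, the clock activator BMAL1, came closest to a call (0.33, adjusted p = 0.0911, edgeR). Kidney proximal tubule markers had a median of −0.42 in ovary and moved with 1 library: they summed to 151 CPM in vehicle replicate 1 and to between 46.2 and 57.3 CPM in the other ovary libraries. Distal kidney markers (median 0.025, mean −0.17), adrenal markers (0.0068, mean −0.25) and podocyte markers (−0.048, with camera on the higher side) likewise differed in sign between measures. Vehicle replicate 2 held 24.3 CPM of the oviduct gene Ovgp1 and 3.85 CPM of the adipocyte hormone gene Adipoq.

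**Figure D2:**
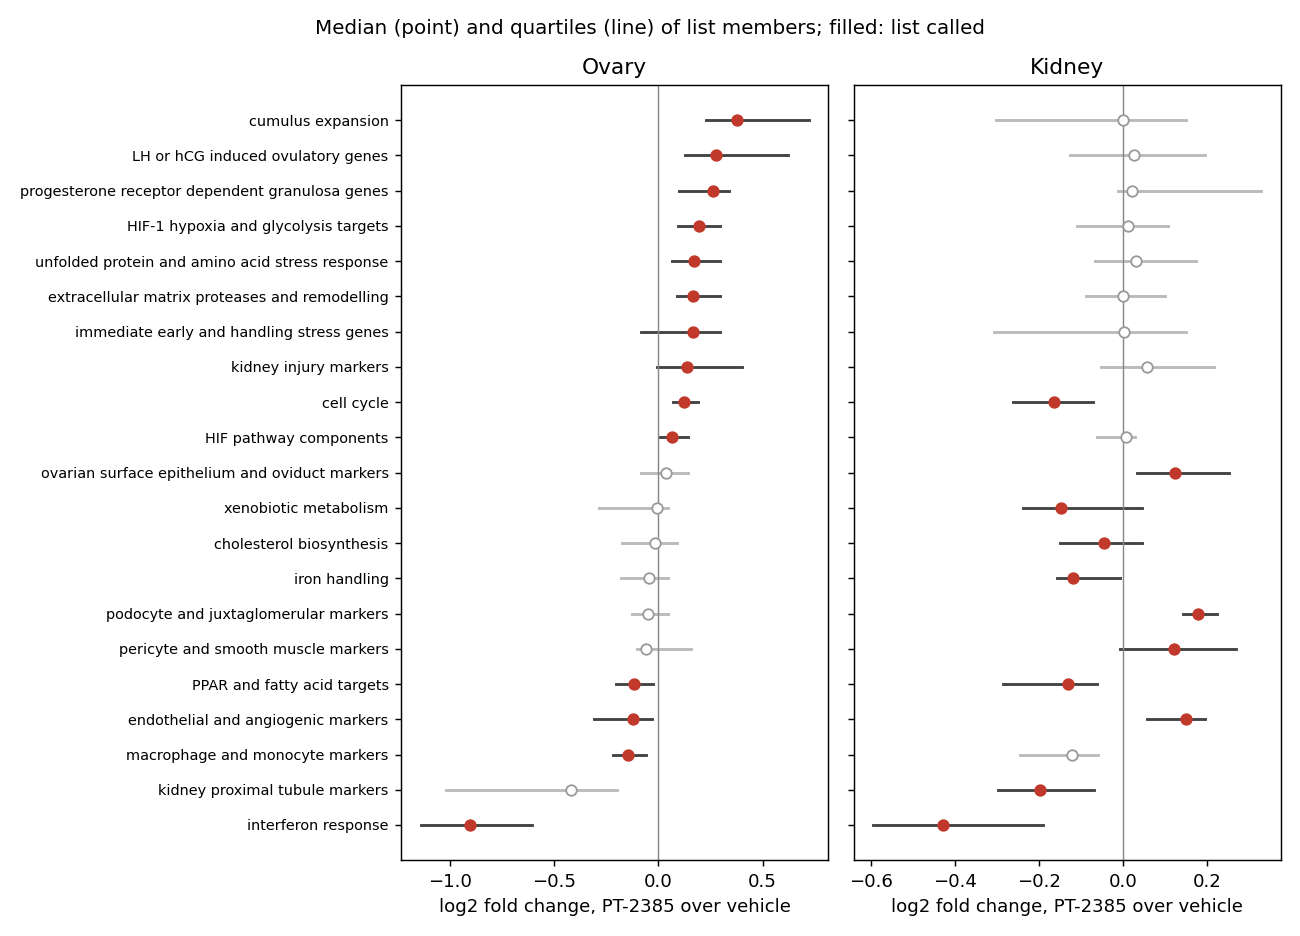
Median log2 fold change of PT-2385 over vehicle for the members of each list called in at least 1 organ, in ovary and kidney; lines span the quartiles and filled points mark lists called by camera. The interferon list has the lowest median in both organs, −0.90 and −0.43.

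The second comparison asked what the same treatment did to the kidney, an organ in which HIF-2α is active in interstitial and vascular cells. Here 1032 of 17763 genes passed, 355 higher and 677 lower, mostly by small amounts: 945 changed by less than 1.5-fold and 18 by more than 2-fold, with a median size of 0.29 on the log2 scale. Cyp51, the sterol demethylase of cholesterol synthesis (chromosome 5, 4131145 to 4154746), fell from 406 ± 40.0 to 273 ± 10.9 CPM (n = 4, log2 fold change −0.57, SE 0.0611, adjusted p = 0.00112, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Cyp2a4, a steroid hydroxylase (chromosome 7, 26006594 to 26014513), fell to 0.349 of vehicle, from 3.03 ± 0.471 to 1.03 ± 0.270 CPM (adjusted p = 0.00151, edgeR). Serpina1a, an α1-antitrypsin gene (chromosome 12, 103819848 to 103829814), rose 1.68-fold, from 17.4 ± 3.13 to 29.1 ± 1.29 CPM (adjusted p = 0.00248, edgeR). Aqp1, the water channel of the proximal tubule (chromosome 6, 55313417 to 55325540), fell from 933 ± 85.3 to 720 ± 16.5 CPM (log2 fold change −0.37, SE 0.0582, adjusted p = 0.00399, edgeR).

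The ranks given next cover called genes with a proper symbol, at least 2 CPM in the higher group and no overlap between groups. Besides Serpina1a, the largest rises in kidney were those of Hist1h1d, a linker histone (log2 fold change 1.53), Nr2e3, a nuclear receptor (0.95), Prkag3, a regulatory subunit of AMP-activated kinase (0.71), Adam11 (0.64), Pik3r6 (0.64), Clec18a (0.60), Lmod1, a smooth muscle actin nucleator (0.59), Ttll3 (0.58) and Igf2bp1, an mRNA-binding protein (0.58). Besides Cyp2a4, the largest falls were those of Ly6f (−1.94), Car5a, a mitochondrial carbonic anhydrase (−1.31), C8a, a complement component (−1.12), and Slc22a7, the organic anion transporter OAT2 (−0.95, 82.3 ± 21.0 to 43.2 ± 7.28 CPM). They were followed by Kcng1 (−0.85), Mfrp (−0.84), Nkain1 (−0.82), Erbb3, a receptor of neuregulins (−0.81, 143 ± 17.0 to 82.4 ± 16.7 CPM), and Chst7, a sulfotransferase (−0.79). Of these 20 genes, 11 were called whichever library was left out: Hist1h1d, Nr2e3, Serpina1a, Adam11, Lmod1, Ttll3, Igf2bp1, Cyp2a4, Mfrp, Nkain1 and Chst7. The calls lost numbered 9 without PT-2385 replicate 3, 7 without vehicle replicate 2, 7 without PT-2385 replicate 4, 5 without PT-2385 replicate 1, 2 without vehicle replicate 4, 2 without PT-2385 replicate 2 and 1 without vehicle replicate 1, with adjusted p of up to 0.171, that of Ly6f (edgeR). In a fit of all 16 libraries of both organs Pik3r6 (0.191), Ttll3 (0.0892) and Kcng1 (0.224) lost their calls, and with 1 surrogate variable Hist1h1d (0.0533), Clec18a (0.101), Car5a (0.0759) and Erbb3 (0.091) did. With no filter Ly6f (0.124), C8a (0.102), Slc22a7 (0.0847) and Erbb3 (0.0514) lost theirs. Ly6f and Slc22a7 also did with median-ratio size factors (0.0525 and 0.0518) and without mitochondrial and haemoglobin genes (0.0518 and 0.0504), Slc22a7 with the legacy test (0.0504) and C8a with the block on replicate number (0.104). DESeq2 gave no adjusted p for Hist1h1d, Nr2e3, Prkag3, Cyp2a4 and Car5a. The total of 1032 fell to 231, 289, 292 and 569 without PT-2385 replicate 3, vehicle replicate 2, PT-2385 replicate 4 and PT-2385 replicate 1. Serpina1a, Cyp2a4 and Ly6f belong to families of near-identical genes, and Mfrp and Car5a share 31.7% and 25.1% of their exon bases with overlapping gene models, so their reads may include those of a neighbour or copy.

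Markers of the proximal tubule lay lower as a list in kidney. Of 22 measured members, 21 had lower values, 8 fell over all genes and 13 fell adjusted over the list alone, with a median log2 fold change of −0.20 (camera adjusted p = 2.94e-09; adjusted p = 0.179 with an estimated correlation). With Aqp1, the members that led were Fbp1, a gluconeogenic phosphatase (819 ± 9.94 to 666 ± 43.8 CPM, n = 4), Ggt1, the brush border γ-glutamyltransferase, and Slc13a3, a dicarboxylate transporter. Their log2 fold changes were −0.30, −0.28 and −0.29 (adjusted p = 0.00466, 0.0075 and 0.0094, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). In the fit of all 16 libraries Fbp1, Ggt1 and Slc13a3 lost the call, with adjusted p of 0.466, 0.387 and 0.521 (edgeR). The list did not move evenly: Slc34a1, the phosphate transporter NaPi-IIa, Miox, the inositol oxygenase, and Kap had log2 fold changes of −0.04, −0.01 and −0.06, and Slc5a2, the glucose transporter SGLT2, 0.19. Per library, the list score was −0.00966, 0.004, 0.0132 and −0.0182 with vehicle and −0.193, −0.103, −0.255 and −0.279 with PT-2385 (two-sided exact permutation p = 0.0286, 0.131 after adjustment over all lists). Here too the unadjusted p is the smallest the design allows.

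Lists of vessel and glomerulus markers were called on the higher side in the same kidneys, although few members passed over all genes. Endothelial markers had a median log2 fold change of 0.15 with 24 of 28 members positive, 3 that rose over all genes and, adjusted over the list alone, 13 that rose and 1 that fell (camera adjusted p = 2.59e-05; adjusted p = 0.445 with an estimated correlation). Those 3 were Sox18 and Sox7, transcription factors of endothelial cells (13.7 ± 1.22 to 19.4 ± 2.73 CPM for Sox18, n = 4), and Cldn5, a tight junction protein, with log2 fold changes of 0.53, 0.56 and 0.26 (adjusted p = 0.00636, 0.00829 and 0.0345, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Podocyte and juxtaglomerular markers had a median of 0.18 with 13 of 14 positive, 2 that rose over all genes and 8 adjusted over the list alone (camera adjusted p = 2.64e-05; adjusted p = 0.445 with an estimated correlation). These were Wt1, the podocyte transcription factor (0.27), and Synpo, synaptopodin (0.28). Pericyte and smooth muscle markers had a median of 0.12 with 12 of 16 positive and 3 that rose over all genes, Lmod1, Myh11, smooth muscle myosin (0.26), and Des, desmin (0.30). Adjusted over the list alone, 3 rose and 1 fell (camera adjusted p = 0.00247; adjusted p = 0.445 with an estimated correlation). In the fit of all 16 libraries Sox18 (adjusted p = 0.0553), Sox7 (0.0541), Cldn5 (0.324), Wt1 (0.124), Synpo (0.143), Myh11 (0.371) and Des (0.722, edgeR) lost their calls, and with 1 surrogate variable Cldn5, Wt1, Synpo, Myh11 and Des did (0.0855 to 0.144), so that of the 8 only Lmod1 kept its call in both. The list of ovarian surface and oviduct markers rests in kidney on epithelial genes such as Krt18 (0.24) and on Sox17 (0.29). It had a median of 0.12 with 14 of 17 positive and 0 changed over all genes or adjusted over the list alone (camera adjusted p = 0.011; adjusted p = 0.445 with an estimated correlation). It lost its call without vehicle replicate 1 (0.0608).

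Interferon response genes lay lower in kidney as well, by less than in ovary. Of 28 members 27 had lower values, 2 fell over all genes and 11 fell adjusted over the list alone, with a median log2 fold change of −0.43 (camera adjusted p = 2.94e-09; adjusted p = 0.445 with an estimated correlation). Gbp3, a guanylate-binding protein, fell from 34.8 ± 5.54 to 22.9 ± 2.43 CPM (n = 4, log2 fold change −0.62, SE 0.111, adjusted p = 0.0116, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment) and Ifit3b by 0.41 on the log2 scale. Irf7, the interferon regulatory factor, had −0.75 and narrowly missed the threshold (adjusted p = 0.0508, edgeR). Per library, the list score was 0.0412, −0.37, 0.0282 and 0.282 with vehicle and −0.451, −0.293, −0.417 and −0.277 with PT-2385, so that vehicle replicate 2 lay among the treated kidneys (two-sided exact permutation p = 0.0857, 0.305 after adjustment over all lists).

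The other lists that were lower in kidney held metabolic and cell cycle genes. Iron handling genes had a median log2 fold change of −0.12 with 4 of 20 positive, 3 that fell over all genes and 5 adjusted over the list alone (camera adjusted p = 0.00655; adjusted p = 0.22 with an estimated correlation). The first 3 were Aco1, the iron-sensing aconitase (445 ± 7.36 to 377 ± 12.5 CPM, n = 4), Steap3, a ferrireductase, and Slc11a2, the iron transporter DMT1, at −0.24, −0.36 and −0.27. The median of iron handling genes was −0.077, −0.057 and −0.061 without vehicle replicates 1, 2 and 4. Xenobiotic metabolism genes had a median of −0.15 with 8 of 24 positive and 4 that fell over all genes, with 2 up and 7 down adjusted over the list alone (camera adjusted p = 0.0157; adjusted p = 0.22 with an estimated correlation). Abcc2, an organic anion exporter (−0.40), and Tiparp, a target of the aryl hydrocarbon receptor (−0.28), led it. The call was lost without vehicle replicate 4 (0.0683), and the median was −0.093 without vehicle replicate 2. PPAR and fatty acid targets had a median of −0.13 with 4 of 23 positive, and 1 that fell over all genes and adjusted over the list alone (camera adjusted p = 0.0024; adjusted p = 0.805 with an estimated correlation). The call was lost without PT-2385 replicate 3 (0.0725), and the median was −0.22 without vehicle replicate 4. Cell cycle genes such as Mcm6, a replication helicase subunit (−0.20), had a median of −0.16 with 4 of 30 positive and 0 changed over all genes or adjusted over the list alone (camera adjusted p = 0.00725; adjusted p = 0.805 with an estimated correlation). Their call was lost without vehicle replicate 3 (0.0928), PT-2385 replicate 2 (0.15) or PT-2385 replicate 3 (0.102, median −0.061), and their median was −0.29 without PT-2385 replicate 1. Genes of cholesterol biosynthesis in kidney split: 3 fell over all genes, among them Cyp51 and Sqle, squalene epoxidase (−0.23). Adjusted over the list alone 4 fell, and 11 of 26 members were positive, with a median of −0.045 (camera adjusted p = 0.0285; adjusted p = 0.805 with an estimated correlation). That last call was lost without vehicle replicate 3 (camera adjusted p = 0.0553), vehicle replicate 4 (0.314), PT-2385 replicate 1 (0.346, median 0.012) or PT-2385 replicate 3 (0.0563), and with the block on replicate number (0.0638). With 1 library left out the median of cholesterol biosynthesis ran from −0.11 to 0.012, so it changed sign.

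The hypoxia lists were not called in kidney. Targets preferred by HIF-2α had a median log2 fold change of 0.040, a mean of −0.064 and camera on the lower side (adjusted p = 0.688). Aqp1, Slc11a2 and Ndrg1, a stress-induced gene (2449 ± 174 to 2075 ± 136 CPM, n = 4, log2 fold change −0.24, adjusted p = 0.0303, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment) fell, while Loxl2, a collagen cross-linking oxidase, rose (0.20). HIF-1 and glycolysis targets had a median of 0.011 with camera on the lower side (camera adjusted p = 0.946). Bnip3 and Bnip3l, mitophagy receptors (−0.26 and −0.20), and Pgk1, a glycolytic kinase (−0.16), fell. Bnip3 shares 27.2% of its exon bases with an antisense gene model, so its reads may include those of its neighbour. Of the HIF pathway list (median 0.0069, mean −0.0087, lower by camera, adjusted p = 0.685), Cited2, a HIF antagonist, fell by 0.38 on the log2 scale. Clock genes (median −0.055, mean 0.046, lower by camera, adjusted p = 0.779) went both ways, with Per2 higher (0.61) and Npas2 (−0.35) and Rora (−0.42) lower. Single members passed in further lists without a call: Csf1r, the macrophage growth factor receptor, fell (−0.27; list median −0.12, camera adjusted p = 0.0759), as did Aqp4, a collecting duct water channel (−0.35), while Pvalb of the distal tubule rose (0.30; list median 0.071, camera adjusted p = 0.136). Klf2, an endothelial factor that responds to flow (0.49), Ddit3, the stress factor CHOP (0.49), Clu, clusterin (0.23), and Plat, a plasminogen activator (0.32), rose, and Cth, a cysteine-producing enzyme (−0.30), Plau, urokinase (−0.32), Por, the electron donor of cytochromes P450 (−0.36), and Prlr, the prolactin receptor (−0.35), fell. Their lists were not called, with medians of 0.0022 for immediate early genes, 0.032 for the unfolded protein response, 0.056 for injury markers, 0.00093 for matrix genes and −0.016 for steroidogenesis. Havcr1, the injury marker KIM-1, had −0.61 and missed the threshold (adjusted p = 0.114, edgeR).

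Many list members selected in kidney depended on single libraries. Of the 42 that passed, 15 did so whichever library was left out, among them Aco1, Aqp1, Cth, Cyp51, Fbp1, Gbp3, Ggt1, Klf2, Plau, Por, Slc11a2, Slc13a3, Sox18 and Steap3. The number lost was 25 without PT-2385 replicate 3, 22 without PT-2385 replicate 4, 20 without vehicle replicate 2, 11 without PT-2385 replicate 1, 9 without vehicle replicate 1, 8 without PT-2385 replicate 2, 3 without vehicle replicate 4 and 2 without vehicle replicate 3. Counting all genes selected in kidney, 32 lost their call in the fit of all 16 libraries and 24 with 1 surrogate variable, against at most 8 in any other setting with all libraries kept. Besides the tubule, vessel and glomerulus markers given above, the list members lost in the fit of 16 were Abcc2, Bnip3l, Plat, Cth, Gbp3, Sqle, Aqp4, Plau, Pvalb, Ifit3b, Csf1r, Clu, Bnip3, Prlr, Klf2, Cited2, Ndrg1, Loxl2 and Pgk1, with adjusted p from 0.0513 to 0.423 (edgeR). With 1 surrogate variable Ddit3 and Rora were lost too (0.0623 and 0.0757). With no filter Cldn5 (0.0511), Cited2 (0.0645), Loxl2 (0.0804) and Prlr (0.164) lost theirs, and with the block Cited2 (0.0685) and Pgk1 (0.0508) did. Prlr was lost with median-ratio size factors (0.0507) and limma-voom (0.0518), and Loxl2 with upper-quartile scaling (0.0537). The composition of the kidney libraries separated both groups as well, alongside the tubule and vessel lists. The mitochondrial share of counts was 11% ± 0.735 with vehicle and 12.2% ± 0.348 with PT-2385, the share of the 10 highest genes 15.1% ± 0.934 and 16.2% ± 0.301, and that of lincRNA 0.598% ± 0.0167 and 0.631% ± 0.00926 (n = 4, two-sided exact permutation p = 0.0286 each, 0.133 after adjustment over 14 such tests). Each unadjusted p is the smallest the design allows. The other kidney lists, for which oocyte and adrenal markers were not tested, had medians between −0.016 for erythroid and 0.23 for adipocyte markers and adjusted p of 0.282 or more. Median, mean and camera differed in sign for LH or hCG genes (0.027, −0.011, higher), matrix genes (0.00093, −0.016, lower), theca markers (0.079, −0.018, higher), immediate early genes (0.0022, −0.085, higher) and neutrophil markers (0.039, 0.0088, lower).

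**Figure D3:**
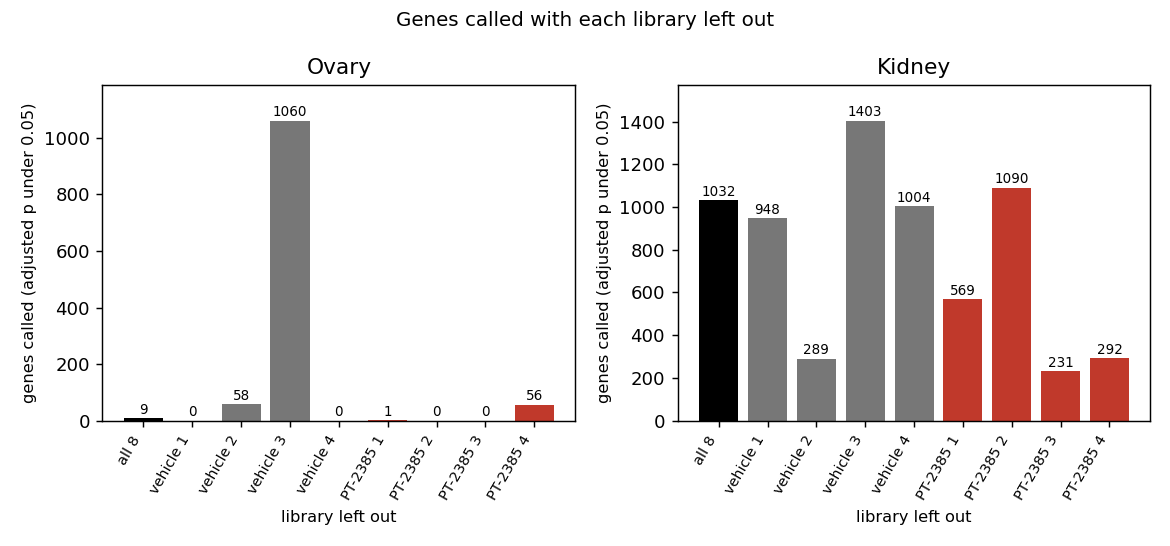
Number of genes called at an adjusted p under 0.05 with all 8 libraries of an organ (black) and with each one left out (grey vehicle, red PT-2385). In ovary the count runs from 0 to 1060, the last without vehicle replicate 3, and in kidney from 231 to 1403.

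The third comparison asked whether the 2 organs answered differently. Over 15816 genes tested in both, the log2 fold changes of ovary and kidney correlated weakly (Pearson r = 0.13, Spearman correlation = 0.128, across genes, which are not independent replicates), and 54.5% had the same sign. Slc11a1, the 1 gene that rose in ovary, and the 8 that fell there were not among the calls of the same direction in kidney (0.0209 and 0.3 shared genes for independent lists). This depended on single libraries. Without ovary vehicle replicate 2, ovary PT-2385 replicate 4 or ovary vehicle replicate 3, 8, 9 and 48 genes fell in both organs, against 1.61, 1.54 and 16.6 for independent lists (Fisher exact p = 0.00017, 1.65e-05 and 3.43e-11, over genes that are not independent). Without ovary vehicle replicate 3, 25 rose in both (11.6 for independent lists, Fisher exact p = 0.000283). Without ovary PT-2385 replicate 1 or kidney vehicle replicate 3, 1 gene fell in both, and without any other library none did. Stk32a, a serine/threonine kinase (chromosome 18, 43340648 to 43451747), led the genes whose response differed. It went from 2.86 ± 0.164 to 5.40 ± 0.952 CPM in ovary and 7.93 ± 0.525 to 6.46 ± 0.691 CPM in kidney (n = 4). The difference was 1.22 on the log2 scale (SE 0.174, adjusted p = 0.00916, edgeR quasi-likelihood test of the interaction with Benjamini-Hochberg adjustment).

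In total 32 of 19977 genes were called as different between organs, 27 with the higher response in ovary and 5 with the lower. Chance was not excluded for this count, as 3 of 60 regroupings of the libraries, the real one included, reached it. Regrouping breaks the treatment groups within an organ, so it does not model an equal response in both organs and cannot decide this. Further genes of the first kind were Arid5b, a chromatin factor of adipogenesis (difference 0.57), Por (0.60), Arhgap11a (0.63), Fam189a2 (0.74), Pdxk, pyridoxal kinase (0.63), and Gramd1b, a sterol transfer protein of the endoplasmic reticulum (0.68), with adjusted p between 0.0295 and 0.0323 (edgeR quasi-likelihood test, Benjamini-Hochberg). Por fell in kidney (−0.36) and had 0.22 in ovary, short of a call. Those with the lower response in ovary were Cmpk2 (−0.95), Trim34a (−1.01), Slfn5 (−0.78), Sgk1 (−0.74) and Itpr3 (−0.54). The last 3 were named after their values were seen. The share with the higher response in ovary was 84.4% and moved with the settings: 75% of 20 genes with median-ratio size factors, 68.8% of 16 genes with upper-quartile scaling and 60.5% of 304 genes with DESeq2, which changes the test too. It was 52.9% of 17 genes with a block on replicate number, where Por and Arid5b lost their calls (adjusted p = 0.0693 and 0.0681, edgeR), and 60.7% of 758 genes without ovary vehicle replicate 3. With 1 surrogate variable 2 genes remained, and Stk32a (adjusted p = 0.0591), Por (0.0944), Arid5b (0.101), Arhgap11a (0.101), Fam189a2 (0.115), Gramd1b (0.123) and Pdxk (0.146, edgeR) lost their calls. Pdxk shares 41.1% of its exon bases with an antisense gene model, so its reads may include those of its neighbour. Of the 8 calls of smallest p, all were lost without ovary PT-2385 replicate 3 (0 genes called), 6 without each of ovary vehicle replicate 1 (2 called), kidney vehicle replicate 2 (2), kidney PT-2385 replicate 3 (2) and kidney PT-2385 replicate 4 (2). The number lost was 5 without each of ovary PT-2385 replicate 1 (3), ovary PT-2385 replicate 2 (4) and kidney PT-2385 replicate 1 (5), and 1 without kidney vehicle replicate 1 (18) and without kidney vehicle replicate 3 (9). The count was 21 without ovary vehicle replicate 4 and 18 without kidney vehicle replicate 4.

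As lists, 12 differed between organs by camera, 7 higher and 5 lower in ovary, and none with an estimated correlation, where adjusted p was 0.465 or 0.621. Interferon genes fell further in ovary (median difference −0.44 on the log2 scale, 25 of 28 members negative, 9 adjusted over the list alone; camera adjusted p = 1.51e-09, adjusted p = 0.465 with an estimated correlation). Endothelial markers differed by −0.25, podocyte markers by −0.25 and pericyte markers by −0.095, all lower in ovary (camera adjusted p = 3.1e-08, 0.0152 and 0.0152; adjusted p = 0.465 with an estimated correlation). Cell cycle genes differed by 0.26, with 29 of 30 members higher in ovary, cumulus expansion genes by 0.36, LH or hCG genes by 0.34 (25 of 32 higher), HIF-1 and glycolysis targets by 0.19, matrix genes by 0.19, HIF pathway genes by 0.15 and unfolded protein response genes by 0.15. In that order their camera adjusted p was 9.35e-08, 0.00157, 0.00979, 9.35e-08, 0.00211, 0.0251 and 0.00155, and 0.0468 for distal kidney markers. The HIF pathway list includes Pgr. Only 11 of 16 cumulus expansion genes and 23 of 32 LH or hCG genes had enough counts to be tested in kidney alone. The others entered this comparison with low kidney counts, so their differences are less certain. Distal kidney markers differed by −0.96, but by −0.0128 without ovary vehicle replicate 1 (camera adjusted p = 0.971), the library that held kidney transcripts. That call was also lost without kidney PT-2385 replicate 1 (0.0631), kidney vehicle replicate 1 (0.0554), kidney vehicle replicate 2 (0.0826), kidney vehicle replicate 4 (0.0501), ovary PT-2385 replicate 1 (0.102), ovary PT-2385 replicate 3 (0.147) or ovary PT-2385 replicate 4 (0.0803), and with the stricter filter (0.0501). The LH or hCG call was lost without ovary vehicle replicate 2 (0.0751), and the podocyte call without kidney vehicle replicate 1 (0.0554) or ovary vehicle replicate 3 (0.0618), and without both libraries with deviating file names (0.129, a fit added after the data were seen). The pericyte call was lost without kidney PT-2385 replicate 2 (0.0562), ovary PT-2385 replicate 1 (0.111) or ovary PT-2385 replicate 4 (0.0507), and the HIF pathway call without kidney PT-2385 replicate 1 (0.0511), kidney vehicle replicate 1 (0.0554), ovary PT-2385 replicate 3 (0.114) or ovary vehicle replicate 2 (0.114). With a block on replicate number the calls of HIF pathway components (0.0512), distal kidney markers (0.22) and pericyte markers (0.0735) were lost. With 1 library left out, medians ran from 0.19 to 0.411 for LH or hCG genes, 0.105 to 0.256 for HIF-1 targets, 0.0865 to 0.223 for the unfolded protein response, 0.0726 to 0.209 for the HIF pathway, 0.196 to 0.61 for cumulus expansion, 0.172 to 0.418 for the cell cycle and 0.15 to 0.27 for matrix genes. They ran from −0.291 to −0.0339 for pericyte, −0.295 to −0.173 for endothelial and −0.272 to −0.204 for podocyte markers and from −0.542 to −0.346 for interferon genes. Lists that were not called included targets preferred by HIF-2α (median 0.020, camera adjusted p = 0.286), steroidogenesis (0.13, 0.177), proximal tubule markers (−1.10, 0.0805) and progesterone receptor dependent genes (0.13 with a mean of −0.057, 0.149). The value of proximal tubule markers includes ovary vehicle replicate 1, whose score for them was 1.14 against −0.419 to −0.356 in the other vehicle ovaries.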

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

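Among 394 groups of 4 libraries checked for a value far from the other 3, 15 held one (3.81%), where chance gives about 1 in 20, or 20. The number that follows each is the gap to the nearest other value as a share of the whole range. Depth stood apart in ovary vehicle replicate 3 (33.6 against 29.5 to 29.8 M, 0.938) and kidney vehicle replicate 3 (23.3 against 26.3 to 27.0 M, 0.833). List scores stood apart for proximal tubule markers in ovary vehicle replicate 1 (1.14 against −0.419 to −0.356, 0.96), lymphocyte markers in ovary PT-2385 replicate 1 (0.0498 against −0.15 to −0.128, 0.887) and clock genes in ovary PT-2385 replicate 4 (−0.06 against 0.073 to 0.0988, 0.837). They also did for HIF-2α targets in kidney PT-2385 replicate 1 (−0.107 against 0.0452 to 0.0676, 0.872) and theca markers in kidney vehicle replicate 3 (−0.123 against −0.0137 to −0.00395, 0.918).

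Single genes stood apart in the same way, in CPM. In ovary these were Adamts4 in PT-2385 replicate 3 (225 against 162 to 171, 0.856) and Serpina3n in PT-2385 replicate 1 (85.3 against 101 to 103, 0.856). In kidney they were Chst7 in vehicle replicate 1 (6.44 against 4.33 to 4.51, 0.916) and in PT-2385 replicate 1 (3.11 against 2.75 to 2.8, 0.87), Slc13a3 in PT-2385 replicate 1 (460 against 509 to 518, 0.841), Wt1 in PT-2385 replicate 3 (33.1 against 31 to 31.2, 0.907), Mcm6 in vehicle replicate 4 (33.7 against 37.2 to 37.6, 0.897) and Tiparp in PT-2385 replicate 2 (28.3 against 24.9, 0.998).

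Other results stood out because the response differed between ovary and kidney. Among genes these included Stk32a (1.22), Fam189a2 (0.74), Gramd1b (0.68), Arhgap11a (0.63), Pdxk (0.63), Por (0.60) and Arid5b (0.57), as log2 fold change in ovary minus kidney. Among lists the medians were −0.957 for distal kidney markers, −0.44 for interferon genes, −0.252 for endothelial, −0.249 for podocyte and −0.0953 for pericyte markers. They were 0.362 for cumulus expansion, 0.335 for LH or hCG genes, 0.262 for the cell cycle, 0.194 for HIF-1 targets, 0.19 for matrix genes, 0.151 for the HIF pathway and 0.15 for the unfolded protein response.

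All tests below were chosen after the results were seen, except the regroupings of the interaction and the fits with 1 library left out, which were planned. The number of genes called in ovary rested on vehicle replicate 3. A wrong treatment label could produce this: the library's median position between vehicle (0) and PT-2385 (1) was 0.878 over 500 genes but −0.0833 over the interferon list, so the test cannot tell. An unusual RNA composition fits: noncoding minus coding genes deviated by −0.463 log2 units, against −0.1 to 0.27 in the other 7 ovary libraries. No biological explanation was tested.

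Interferon genes were lower with PT-2385 in both organs. Fewer immune cells may underlie this: the interferon score fell further than that of macrophage markers by 0.766 in ovary (difference −0.766, two-sided exact permutation p = 0.0571) and by 0.234 in kidney (−0.234, exact p = 0.2), which cannot decide it. Macrophage and lymphocyte scores changed by −0.141 and −0.108 in ovary and by −0.121 and 0.105 in kidney. An interferon state of single mice, shared by organs of the same number, might also be at work: within-group deviations had Pearson r = 0.698 over 8 pairs (exact permutation p = 0.0451, 0.649 after Benjamini-Hochberg over 32 lists) and Spearman correlation = 0.786 (exact permutation p = 0.0451, 0.514 adjusted), with r = 0.562 without the 2 farthest pairs. With 576 possible pairings and 32 lists, a single list could not reach an adjusted p under 0.05 even at its smallest p. The adjusted values therefore cannot decide it either.

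Proximal tubule markers were lower in kidney while vessel and podocyte markers were higher. A smaller share of proximal tubule cells could give both. The 22 members moved by unlike amounts, 21 lower and 1 higher (heterogeneity 86.8 on 21 degrees of freedom, chi-square test over genes, p = 5.66e-10). An even loss of these cells alone would lower the members alike. However, the members come from the same libraries and are not independent, and a loss need not be even, so the test cannot decide it. Macrophage minus endothelial scores changed by −0.251 (two-sided exact permutation p = 0.114). The other flow cell of kidney PT-2385 replicate 3 does not account for it, as the list median was −0.2 without that library (camera adjusted p = 7.92e-09).

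Regrouping the libraries tested whether chance could be excluded. For ovary genes 1 of 35 splits, the real one, reached its 9 calls, and the highest other count was 0. At an unadjusted p of 0.05, though, 3 other ovary splits held more genes (3872, 3378 and 3257) than the real 2375. Each placed vehicle replicate 3 with 3 PT-2385 libraries, and only the adjusted count sets the real split apart. For kidney genes it was also 1 of 35, with 1032 calls against at most 2. For lists chance could not be excluded: in ovary 16 of 35 splits called at least the real 14 (highest other 17), in kidney 4 of 35 at least the real 11 (highest other 11) and for the interaction 19 of 60 at least the real 12 (highest other 16). For interaction genes 3 of 60 regroupings, the real one included, reached the real 32. By the share of 0.05 set beforehand, chance could not be excluded here either. Another of them called 68, with the ovary groups kept and only the kidney libraries regrouped. The highest called 339. That one kept the kidney groups and exchanged ovary vehicle replicate 3 and ovary PT-2385 replicate 1. The exchange points to a structure of the ovary samples around vehicle replicate 3. A wrong label on that library would give the same, and its cause was left open above. Both regroupings kept the real groups of an organ, and regrouping within organs does not model an equal response in both. They thus cannot decide whether chance gave the interaction counts.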

How the results depend on the processing

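Direction held almost everywhere and calls did not. For 1 result the direction of camera reversed: the distal kidney list between organs without ovary vehicle replicate 1, where the median kept its sign at −0.0128 (−1.18 at the other end with 1 library left out). The median of cholesterol biosynthesis in kidney changed sign, to 0.0124, without PT-2385 replicate 1, while the direction of camera held. Ovary genes called (9) became 322 with DESeq2, 3 with limma-voom, 63 with no filter, 5 with the stricter filter, 33 with 1 surrogate variable and 364 in the fit of 16 libraries. Leaving out 1 library gave 0 to 1060: 0 without vehicle replicate 1, vehicle replicate 4, PT-2385 replicate 2 or PT-2385 replicate 3, 1 without PT-2385 replicate 1, 56 without PT-2385 replicate 4, 58 without vehicle replicate 2 and 1060 without vehicle replicate 3. Kidney genes (1032) became 599 with 1 surrogate variable and 307 in the fit of 16 libraries, and 231 to 1403 with 1 library left out (231, 289, 292 and 569 the lowest). Interaction genes (32) became 20 with median-ratio factors, 16 with upper-quartile scaling, 304 with DESeq2, 50 with no filter, 2 with 1 surrogate variable and 0 to 758 with 1 library left out (0, 2, 3, 4, 5, 9, 18, 21 and 758), and 344 without both libraries with deviating file names, a fit added after the data were seen. Lists called fell to 0 in ovary, kidney and the interaction with an estimated correlation, and to 0, 3 and 0 with fry. The 3 that fry kept in kidney were proximal tubule markers, iron handling and xenobiotic metabolism, all lower (fry adjusted p = 0.0156 each). The stricter filter ended the calls of HIF pathway components (camera adjusted p = 0.0779) and macrophage markers (0.0644) in ovary and of distal kidney markers between organs (0.0501). With 1 library left out the number of lists called ran from 11 to 16, 9 to 12 and 10 to 16. The correlation between organs (0.13) was 0.245 among genes of at least 10 CPM and 0.093 to 0.177 with 1 library left out. Apart from fewer libraries or genes tested, the cause was not tested.

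The replicate block gave 398 genes in ovary, 1271 in kidney and 17 for the interaction. Nothing in the labels pairs the samples by number. Same-numbered libraries correlated at −0.172 to 0.236 between ovary groups and −0.064 to 0.0522 between kidney groups, and best with their own number in 2 of 4 each. Between ovary and kidney they correlated at 0.0211 to 0.0781 for vehicle and −0.0427 to 0.0905 for PT-2385, best with their own number in 3 of 4 each, a hint from the data and not the design. The block ended the calls of macrophage markers in ovary (camera adjusted p = 0.0506), of cholesterol synthesis in kidney (0.0638) and of the kidney genes C8a, Cited2 and Pgk1 (edgeR adjusted p = 0.104, 0.0685 and 0.0508), and for the interaction those of 3 lists (HIF pathway 0.0512, distal kidney markers 0.22, pericyte markers 0.0735) and of Por and Arid5b (edgeR adjusted p = 0.0693 and 0.0681).

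Of the other values for named genes with 1 library left out, 281 in ovary, 456 in kidney and 79 for the interaction kept direction and side of the threshold, and 40, 133 and 49 became weaker. Under the other settings 410, 723 and 79 kept them, and 10, 80 and 9 became weaker. Values also became stronger: 26 in ovary and 7 in kidney with 1 library left out, and 62 and 20 under the other settings. The sign changed, with no call before or after, for 5 values in ovary and 4 in kidney with 1 library left out. Under the other settings it did for 1 and 2. In kidney PT-2385 replicate 2, at 12.7 M, depth limits genes of few counts most.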

Other observations

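Several ovary genes outside the sections above had values of note, none of them called. Ren1, which encodes renin and is made by theca cells as well as kidney, measured 29.3 CPM with vehicle and 47.9 CPM with PT-2385 (log2 fold change 0.71, adjusted p = 0.116, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Aqp2, a water channel, measured 21.0 and 33.0 CPM (log2 fold change 0.65, adjusted p = 0.0583, edgeR).

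Cyp11b1, an adrenal steroid hydroxylase, lay between 55.6 and 144 CPM in ovary and at 1.83 CPM or less in kidney. Cyp17a1, the androgen-producing enzyme of theca cells, measured 13.3 ± 3.96 CPM in ovary with vehicle and 23 ± 7.65 CPM with PT-2385, after TMM scaling over all 16 libraries. The first principal component of the 500 most variable genes held 35.9% of the variance in ovary and 26.5% in kidney, and the second 20.4% and 19.7%. Between replicates of a group, chi-square per degree of freedom ran from 4.37 to 65.9.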
